A study of Mus musculus with 12 samples.

How the data were processed

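RNA had been extracted from snap-frozen pancreatic tumours of KPC mice with a column kit and sequenced as stranded total RNA after depletion of ribosomal RNA, per the labels. The background strain is given there as a mix of C57BL/6 and 129. Each of the 12 libraries is 1 mouse, and genotype, treatment and replicate number were taken from the sample titles, with 3 mice in each of 4 groups. The values are expected counts per Ensembl gene that the authors made with RSEM on the mouse genome GRCm38 and rounded to whole numbers before the files were deposited. The RSEM version, the aligner, the annotation release and whether counting used strand are not given in the sources used here. RSEM divides a read that maps to several places among them by estimated shares. Every value was whole, and 3 values, for Rn7s1, Col4a1 and Eef1a1, were stored to 3 digits. The whole-series table was not used, since its 12 columns equal the 12 library files.

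Each file held 52636 genes, of which 12076 had no count in any library. Symbols and positions came from GENCODE M21 on GRCm38 by gene ID, which matched 52403 IDs; the 233 IDs without a symbol held 0.0721% of the counts. Totals per library lay between 39388328 and 56559413 counts. Between 29885 and 31499 genes had a count. The 10 most abundant genes held between 13.5% and 18.9% of the counts of a library, and 7SL and 7SK RNA between 5.53% and 9.59%. Floors cover counting error only, and 95% intervals of log2 fold changes come from the edgeR model, which includes the spread between mice. Where all libraries of a group were at 0, a fold is a lower bound against 3 counts per library.

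Genes were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr over the 4 groups left 24065 genes, holding at least 99.865% of the counts of each library. TMM factors lay between 0.897 and 1.09. A robust quasi-likelihood model with 1 mean per group was fitted to all 12 libraries, and the biological coefficient of variation was 46.4%. There were 6 comparisons: genotype in untreated mice, genotype in gemcitabine-treated mice, gemcitabine in each genotype, the difference of the gemcitabine effects, and the genotype average over treatments. The Benjamini-Hochberg adjusted p was taken over all genes tested, with a threshold of 0.05. A ± beside a log2 fold change is its standard error (SE), and a ± beside a CPM value is the SD over 3 mice.

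Gene lists were fixed before the data were examined, from textbook markers. They cover fibrillar collagens and matrix proteins, cross-linking and remodelling enzymes, basement membrane, myofibroblast, inflammatory fibroblast, mesenchymal and TGF-beta genes, cadherins and catenins, and immune, vascular, epithelial, admixture and drug response genes. Of 39 lists 38 had at least 5 measured members and were tested, with 6 to 27 members and a median of 16; the Y-linked list was used as a level only. Of 649 symbols, 643 had a gene in the files and 613 were tested. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists of each comparison. The same test with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. The count of members past the threshold is given over all genes and adjusted over the list alone. The adjustment over a list alone was not corrected for the 38 lists and 6 comparisons, so single members can pass by chance. Medians are of edgeR log2 fold changes unless the log2 CPM scale is named.

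Named genes were chosen by a rule fixed at the same time. Cdh11 comes first; then up to 10 genes in each direction that passed, had no overlap between the groups and were not predicted or RIKEN genes; where fewer than 5 passed in a direction, the smallest p-values up to 5; and for each list up to 4 members with the smallest p. For the genotype average, 1 gene that this rule names is not reported here. Near-identical copies of the called genes were sought in the transcripts of GENCODE M21 with blastn 2.17.0, at 95% identity or more over 50% or more of the transcript, and the counts of a gene and its copies were summed.

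The gene test was checked on simulated counts with known changes in 49 or 50 genes of each size. The changed genes were taken from the more abundant genes tested, so recovery can be lower for genes of low level. Counts were drawn independently for each gene, without shared reads, sex or tissue admixture, so the rates hold for that setting only. At 4-fold it recovered 56% of them for genotype in untreated mice, 42% for gemcitabine in wild-type mice, 52% for gemcitabine in heterozygous mice, 64% for genotype in treated mice, 22% for the difference of effects and 77.6% for the genotype average. At 2-fold it recovered 2%, 4%, 8%, 12%, 0% and 34% in the same order, and at 8-fold 84%, 76%, 74%, 70%, 68% and 98%. False calls made up between 3.23% and 6.25% of the calls.

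Alternatives were DESeq2 size factors, upper quartile normalization, no low-count filter, the Wald test of DESeq2 1.42.0, limma voom with quality weights, only the 2 groups compared, the replicate number as a block, the acinar level or the difference of Xist and Y-linked genes as a covariate, and each library left out in turn. With 1 library of 3 left out, all groups share 1 estimate of the spread. For the gene list tests the Xist and Y-linked covariate was chosen after the data were seen. Other splits of the libraries were tested in all 10 ways for 3 against 3 and in 80 of 200 ways drawn at random for the comparisons of all 4 groups. Correlations between libraries had a median of 0.948 within groups and 0.936 between groups.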

Results

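RNA was sequenced from pancreatic ductal adenocarcinomas of KPC mice, a genetic model of pancreatic cancer. The mice were wild-type (+/+) or heterozygous (+/-) for Cdh11, which encodes cadherin 11, an adhesion protein of fibroblasts and other mesenchymal cells. They were untreated or given gemcitabine, a deoxycytidine analogue used against pancreatic cancer; the dose and schedule are not given in the sources used here. There were 3 mice in each of the 4 groups and 12 libraries in all. The series asks what Cdh11 does to the immune and matrix compartments of the tumours and to the gemcitabine response. Libraries held between 39388328 and 56559413 expected counts, with a median of 45785246, and 24065 genes were tested. The biological coefficient of variation between mice of a group was 46.4%.

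The tumours differed in what tissue and which sex chromosomes they carried. Xist, the RNA of the inactive X chromosome, lay between 1220 and 3395 CPM in 6 libraries, in which 4 Y-linked genes summed to at most 0.743 CPM. In the other 6 libraries the Y-linked genes summed to between 41.0 and 506 CPM. The Xist-high libraries were 2 of the untreated wild-type, 1 of the untreated heterozygous, 3 of the gemcitabine-treated wild-type and 0 of the gemcitabine-treated heterozygous tumours. Genotype and these sex-chromosome genes therefore could not be separated among treated mice. Digestive enzyme genes of acinar cells, the normal exocrine pancreas, summed to 385 ± 396 CPM (SD, n = 3) in untreated wild-type tumours and 50.6 ± 9.33 CPM in untreated heterozygous tumours. In gemcitabine-treated tumours they summed to 161 ± 217 CPM in the wild-type and 51.8 ± 57.1 CPM in the heterozygous group. Islet genes summed to 170 ± 178, 43.8 ± 19.3, 42.0 ± 25.6 and 71.9 ± 56.6 CPM in the same order, and hepatocyte genes to 3200 ± 884, 1329 ± 983, 1742 ± 610 and 1313 ± 666 CPM.

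Cdh11 lies on chromosome 8 (102632095 to 102785642, minus strand, GRCm38). Untreated wild-type tumours had 10221, 12258 and 8374 Cdh11 counts (224 ± 58.8 CPM, SD, n = 3), and untreated heterozygous tumours had 6759, 5326 and 3710 (112 ± 37.5 CPM). The log2 fold change was -1.0, with a 95% interval of -1.81 to -0.18, and did not pass the threshold over all genes (edgeR adjusted p = 0.33). Gemcitabine-treated wild-type tumours had 6505, 2675 and 5116 counts (109 ± 41.7 CPM), and those labelled heterozygous had 5376, 6073 and 3588 (107 ± 34.8 CPM). Their log2 difference was -0.02, with a 95% interval of -0.83 to 0.79, or 0.562-fold to 1.72-fold, so that a halving lay outside the interval (edgeR adjusted p = 0.996). Cdh11 therefore did not separate the treated groups, which are called by their labelled genotype. With gemcitabine the Cdh11 log2 fold change was -1.04 (95% interval -1.86 to -0.22, edgeR adjusted p = 0.56) in wild-type and -0.07 (-0.88 to 0.74, adjusted p = 0.98) in heterozygous mice. The difference of these effects was 0.98, with a 95% interval of -0.17 to 2.12.

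**Figure D1:**
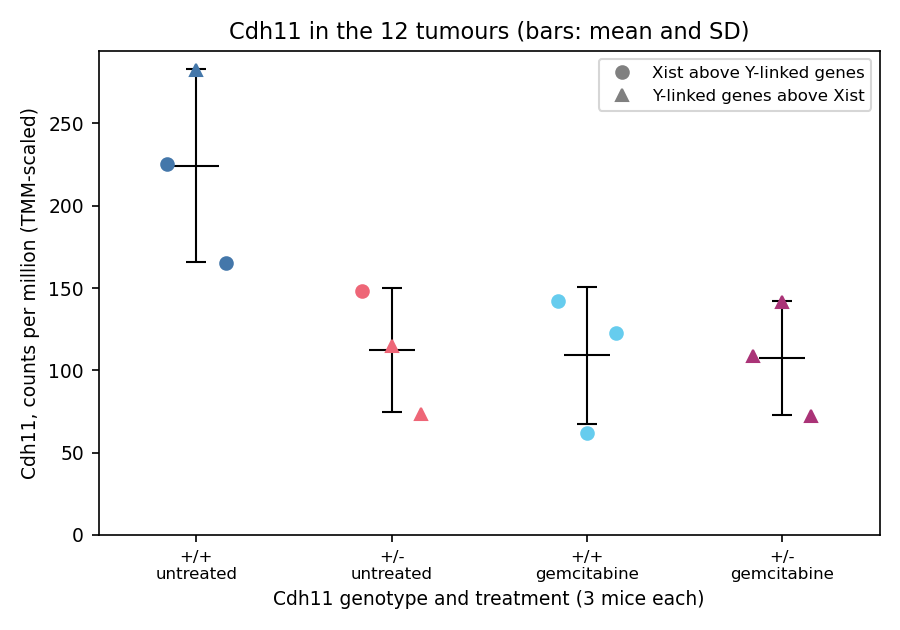
Cdh11 level (CPM) in each of the 12 tumours, by genotype and treatment; horizontal bars are group means with SD (n = 3), and marker shape shows whether Xist or the Y-linked genes were higher. Untreated wild-type tumours lay between 165 and 283 CPM, and the tumours of the other groups between 62.2 and 148 CPM.

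Untreated heterozygous tumours were compared with untreated wild-type tumours to ask what lower Cdh11 does without drug. Genes of the extracellular matrix were lower in the heterozygous tumours. Of 24 fibrillar collagens and matrix proteins, 22 were lower, with a median log2 fold change of -1.13. The list was called lower by camera (adjusted p = 2.8e-10, and adjusted p = 0.28 with an estimated correlation). None of its members passed over all genes, and 14 passed when adjusted over the list alone. The libraries also differed in RNA content, with 7SL and 7SK RNA at 5.53% to 7.87% of the counts in wild-type and 8.19% to 9.59% in heterozygous tumours, and mitochondrial genes at 1.81 ± 0.469% and 2.88 ± 0.876%. Lum, a collagen-binding proteoglycan, was at 187 ± 18.7 CPM (SD, n = 3) in wild-type and 50.8 ± 10.5 CPM in heterozygous tumours, a log2 fold change of -1.88 ± 0.32 (SE). Sparc, Col5a2 and the type I collagen chain Col1a2 had log2 fold changes of -1.08 ± 0.34, -1.16 ± 0.37 and -1.32 ± 0.43, each with adjusted p = 0.045 over the list alone. Of 24 matrix cross-linking and remodelling enzymes 22 were lower, with a median of -1.03 (camera adjusted p = 2.0e-09, and adjusted p = 0.28 with an estimated correlation). Of these, 6 passed when adjusted over the list alone and 0 over all genes, among them the metalloproteinases Mmp10 (-2.97 ± 0.58) and Mmp13 (-5.09 ± 1.32) and fibroblast activation protein, Fap (-1.68 ± 0.41). Of 24 acinar genes 22 were lower (camera adjusted p = 1.2e-09, and adjusted p = 0.32 with an estimated correlation). Their median was -7.60, or -5.43 with the 6 members that had no count in a group set at their bound, and 1 passed as higher and 16 as lower when adjusted over the list alone (0 over all genes). Wild-type mouse 1 had an acinar sum of 29.8 CPM, under the 39.8 to 56.6 CPM of the heterozygous tumours. Islet genes were also lower, with a median of -3.83 over 19 members (camera adjusted p = 1.0e-07, and adjusted p = 0.28 with an estimated correlation); adjusted over the list alone, 1 passed as higher and 13 as lower (0 over all genes).

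Lists of stromal and vascular cells moved with the matrix in the same comparison. Myofibroblast markers were lower for 14 of 16 members, median -1.17, and 7 passed when adjusted over the list alone, including the contractile genes Mylk (-1.41 ± 0.27), Acta2 (-1.31 ± 0.34) and Tagln (-1.21 ± 0.32). Mesenchymal genes were lower for 13 of 15 members, median -0.93, with 5 past the threshold over the list alone, led by the transcription factors Zeb2 (-1.13 ± 0.26) and Prrx1 (-1.75 ± 0.45). Basement membrane genes had a median of -0.79, and 9 of 13 passed over the list alone, among them Nid1 (-1.05 ± 0.27) and Lama1 (-1.73 ± 0.53). Endothelial genes were lower for 15 of 16 members, median -0.87, with 7 past the threshold over the list alone. The vascular cadherin Cdh5 was at 90.5 ± 12.7 CPM in wild-type and 43.3 ± 8.24 CPM in heterozygous tumours (log2 -1.06 ± 0.20), and the TGF-beta co-receptor Eng had -1.28 ± 0.25. All 11 pericyte genes were lower (median -0.79), with 1 past the threshold over the list alone, Pdgfrb (-1.16 ± 0.32). The TGF-beta list had a median of -0.36, with its receptors Tgfbr2 at -0.99 ± 0.27 and Tgfbr1 at -0.83 ± 0.25, and 0 of 18 members past the threshold over the list alone. The cadherin and catenin list had a median of -0.50 (camera adjusted p = 0.015), with Cdh5 the 1 member past the threshold over the list alone. Camera called each of these lists lower, the first 6 at adjusted p between 5.2e-04 and 2.0e-07. With an estimated correlation the adjusted p was 0.28 for all of them. None of their members passed over all genes. Hepatocyte genes were lower as well (median -1.27, camera adjusted p = 0.013, and adjusted p = 0.28 with an estimated correlation), with 0 of 14 members past the threshold over the list alone. Inflammatory fibroblast markers did not pass (median -0.67, adjusted p = 0.064); Pdgfra and Cxcl12 had -1.60 ± 0.50 and -1.63 ± 0.58.

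Among immune lists, macrophage genes were lower for 19 of 20 members (median -0.92, camera adjusted p = 2.9e-04, and adjusted p = 0.55 with an estimated correlation), with the mannose receptor Mrc1 at -1.44 ± 0.48. Neutrophil genes had a median of -0.74 (adjusted p = 0.013, and adjusted p = 0.57 with an estimated correlation), with the calgranulin genes S100a8 and S100a9 at -1.85 ± 0.53 and -2.01 ± 0.67, and dendritic cell genes a median of -0.86 (adjusted p = 0.032, and adjusted p = 0.66 with an estimated correlation). Interferon response genes were higher for 25 of 27 members, median 1.46 (adjusted p = 4.8e-04, and adjusted p = 0.61 with an estimated correlation). The chemokine Cxcl9 had 2, 0 and 1229 counts in the heterozygous and 6, 9 and 4 in the wild-type tumours. Class I presentation genes were higher for 13 of 15 members, median 0.60 (adjusted p = 0.034, and adjusted p = 0.72 with an estimated correlation). H2-T23 (2.21 ± 0.40) and H2-K1 (1.51 ± 0.44), members of a gene family with near-identical copies, passed over the list alone. Duct epithelium genes had a median of 0.36 (adjusted p = 0.020, and adjusted p = 0.57 with an estimated correlation), with the tetraspanin Tspan8 at 0.94 ± 0.33, and Schwann cell genes a median of 0.99 (adjusted p = 0.015, and adjusted p = 0.28 with an estimated correlation), with S100b at 2.32 ± 0.70. Apart from the 2 class I genes, no member of these lists passed over the list alone. T cell (0.13), cytotoxic lymphocyte (0.07), regulatory T cell and checkpoint (0.01), B cell (0.46), plasma cell (0.00) and class II presentation (-0.65) medians were not called, with adjusted p between 0.51 and 0.86. The medians of proliferation (0.27, adjusted p = 0.86), p53 target (-0.20, adjusted p = 0.33) and gemcitabine transport and metabolism genes (0.02, adjusted p = 0.88) were not called either.

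Over all genes, 4 passed the threshold in untreated mice, 1 higher and 3 lower. Trim12a, a TRIM family gene on chromosome 7 (104299894 to 104315466), had 398, 778 and 1018 counts in heterozygous and 7, 16 and 6 in wild-type tumours (log2 6.15 ± 0.58, edgeR adjusted p = 0.0028). Its counts and those of its near-identical copies Trim12c and Trim5 together differed by 0.31 ± 0.31, and the call ended without wild-type mouse 1 and with only these 6 libraries in the model (adjusted p = 0.096). Lrat on chromosome 3 (82892579 to 82903973), which esterifies retinol for storage in stellate cells, had 0, 8 and 6 counts in heterozygous and 330, 382 and 499 in wild-type tumours (log2 -6.43 ± 0.79, adjusted p = 0.029). This call held with heterozygous mouse 1 or wild-type mouse 3 left out and ended without any of the other 4 mice, and it also ended with voom (adjusted p = 0.142), with the acinar covariate (0.183) and with only these 6 libraries in the model (0.197). BC023719, an antisense gene in the class I region of chromosome 17 (36111426 to 36117121), had no count in any untreated heterozygous tumour and was at 4.93 ± 1.69 CPM in wild-type tumours. At 3 counts per library this is at least 77.8-fold lower (edgeR adjusted p = 4.2e-04), a call that ended with voom (adjusted p = 0.051) and with only these 6 libraries in the model (0.122). Together with its copy A930015D03Rik it differed by -1.65 ± 0.37, and whether the counting used strand is not given in the sources used here. Gm10260, chosen after its values were seen because the naming rule leaves out predicted genes, is a near-identical copy of the ribosomal protein gene Rps18 (log2 -7.14 ± 0.45, adjusted p = 1.3e-04); summed over that family the difference was 0.61 ± 0.35. The next smallest p-values did not pass. Snord22, a small nucleolar RNA, had 1.34 ± 0.18 (adjusted p = 0.052), the ribosomal protein genes Rps13 and Rpl34 had 1.98 ± 0.28 and 2.65 ± 0.47, and Qtrt1, which modifies tRNA, had 1.38 ± 0.23. H2-Q1, Draxin and the oxysterol hydroxylase Cyp7b1 had -5.45 ± 0.75, -3.38 ± 0.49 and -2.76 ± 0.42. An unadjusted p under 0.05 was reached by 2928 genes against 1203 expected by chance, and DESeq2 called 703. With the acinar covariate 1438 genes reached it, and with the Xist and Y covariate 2705. Another split of these libraries gave 474 genes by DESeq2. Without heterozygous mouse 3 the interferon median on the log2 CPM scale went from 0.81 to 0.11 and the class I median from 0.37 to -0.28. The interferon, class I, Schwann, neutrophil, TGF-beta and cadherin calls then ended. Without wild-type mouse 2 the macrophage median went from -0.70 to -0.12, and the macrophage, dendritic and duct epithelium calls ended. Of the 19 list calls 9 held with each of the 6 libraries left out in turn, 13 with the acinar covariate and 17 with the Xist and Y covariate.

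**Figure D2:**
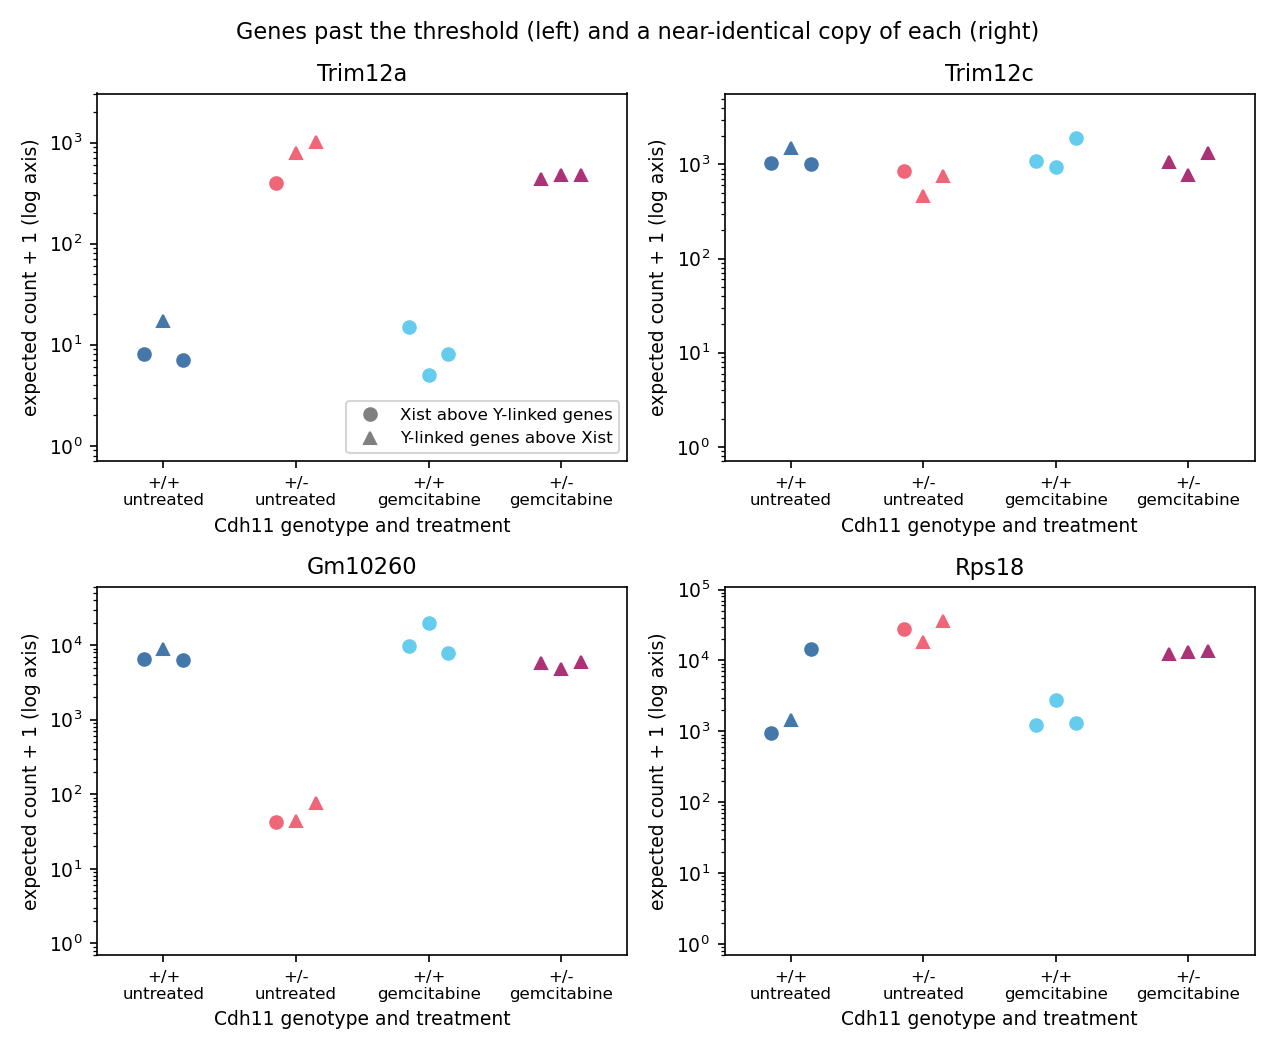
Expected counts plus 1, on a log axis, of Trim12a, its copy Trim12c, Gm10260 and its copy Rps18 in each of the 12 tumours, with marker shape for Xist or Y-linked genes. Trim12a had at most 16 counts in wild-type and at least 398 in heterozygous tumours, while Trim12c had between 465 and 1893 in all; Gm10260 had at most 76 counts in untreated heterozygous tumours, in which Rps18 had at least 17932.

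Gemcitabine-treated tumours labelled heterozygous were compared with treated wild-type tumours to ask what the genotype does under the drug. Genes of lymphocytes, of antibody-secreting cells and of antigen presentation had higher group means in the tumours labelled heterozygous. For lymphocytes and plasma cells these rest on mice 2 and 3, with mean log2 CPM of 2.14 and 1.97 for T cells, 3.11 and 2.33 for B cells and 5.96 and 6.75 for plasma cells. Mouse 1 lay at -0.38, -0.96 and 2.09, against wild-type ranges of -0.73 to -0.41, -1.26 to 0.46 and 1.08 to 2.75. RNA content differed as well, with 7SL and 7SK RNA at 7.78 ± 0.655% of the counts in the labelled heterozygous and 8.47 ± 0.170% in the wild-type tumours, and the noncoding RNA Gm26917 at 0.320% to 0.729% and 0.829% to 3.33%. T cell genes were higher for 17 of 19 members, median 2.16 (camera adjusted p = 7.4e-09, and adjusted p = 0.42 with an estimated correlation, as for the other lists of this paragraph), and 8 passed when adjusted over the list alone. The median weighs members of low level as much as abundant ones. Summed T cell genes overlapped, at 137, 200 and 151 CPM in the labelled heterozygous and 162, 74.6 and 165 CPM in the wild-type tumours. B cell and plasma cell sums in labelled heterozygous mice 2 and 3 exceeded every wild-type tumour. The co-stimulator Cd28 was at 2.97 ± 2.11 CPM against 0.292 ± 0.0582 CPM (SD, n = 3; log2 3.33 ± 0.71), and the T cell receptor component Cd3e had 4.82 ± 1.29. Plasma cell genes were higher for 13 of 14 members, median 3.90 (adjusted p = 3.5e-07), with 10 past the threshold over the list alone, including the antibody genes Ighg2c (8.67 ± 2.02), Igha (3.63 ± 0.96) and Igkc (4.87 ± 1.36). Ighg2c had 87, 2199 and 31284 counts in the labelled heterozygous and 11, 51 and 10 in the wild-type tumours. B cell genes had a median of 2.42 (adjusted p = 5.8e-07), with Ms4a1, the CD20 gene, at 3.92 ± 1.22 and 0 past the threshold over the list alone. All 12 class II presentation genes were higher, median 2.02 (adjusted p = 1.4e-07), and H2-Eb1 alone passed over the list (6.88 ± 1.42). All 15 class I genes were higher, median 0.77 (adjusted p = 6.8e-06), and H2-T23 alone passed over the list (2.30 ± 0.40). With the Xist and Y covariate the class I median on the log2 CPM scale was 0.02 (adjusted p = 0.951) and the class II median 0.31 (0.154), and both calls ended. No member of these lists passed over all genes. The list calls held with each of the 6 libraries left out in turn for T cells, B cells, plasma cells and class II presentation.

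Myeloid lists were higher in the same comparison. Macrophage genes were higher for 19 of 20 members, median 0.92 (adjusted p = 6.0e-06, and adjusted p = 0.42 with an estimated correlation), with the receptor genes Csf1r at 1.10 ± 0.45 and Msr1 at 1.04 ± 0.39. Neutrophil genes had a median of 0.92 (adjusted p = 0.0015, and adjusted p = 0.48 with an estimated correlation). Of these, 2 passed when adjusted over the list alone, the activating receptor Trem1 (1.87 ± 0.34) and lipocalin 2, Lcn2 (1.94 ± 0.47). Dendritic cell genes had a median of 1.17 (adjusted p = 1.3e-05), cytotoxic lymphocyte genes 1.86 (adjusted p = 4.5e-04) and regulatory T cell and checkpoint genes 0.61 (adjusted p = 4.5e-04). The adjusted p was 0.42 with an estimated correlation for all 3; Wdfy4 (1.96 ± 0.50) passed over the dendritic list alone. The checkpoint genes Pdcd1 and Ctla4 were at 2.29 ± 0.77 and 3.71 ± 1.29 and did not pass. All 3 treated tumours labelled heterozygous were Y-high and all 3 wild-type were Xist-high, and with the difference of Xist and Y-linked genes in the model 4 of these 10 lists of immune cells and antigen presentation stayed called. The interferon response list (median -0.32, adjusted p = 0.50) and the cytokine list (0.28, adjusted p = 0.92) were not called. Treated heterozygous mouse 1 lay within the wild-type range of mean log2 CPM for macrophages (5.97, wild-type 4.95 to 6.23), neutrophils (3.21, wild-type 1.82 to 3.57) and dendritic cells (1.12, wild-type 0.66 to 1.26), and under it for cytotoxic lymphocytes (-2.77, wild-type -2.76 to -2.39). Matrix lists were not called: fibrillar collagens and matrix proteins had a median of -0.07 (adjusted p = 0.87), cross-linking and remodelling enzymes 0.04 (0.77), basement membrane -0.07 (0.75) and myofibroblast markers 0.06 (0.88).

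Lower in the treated tumours labelled heterozygous were epithelial, glycolytic and acinar genes. Duct epithelium genes were lower for 20 of 22 members, median -0.58 (adjusted p = 2.2e-05, and adjusted p = 0.42 with an estimated correlation), with E-cadherin, Cdh1, at -0.96 ± 0.25 and the keratin Krt19 at -1.13 ± 0.42. Glycolysis and hypoxia genes were lower for 22 of 23 members, median -0.72 (adjusted p = 2.4e-04, and adjusted p = 0.59 with an estimated correlation). Only the carbonic anhydrase Car9 passed over that list (-1.72 ± 0.42, 13.8 ± 5.32 CPM against 45.2 ± 6.21 CPM). Immediate early and stress genes had a median of -0.59 (adjusted p = 0.0035, and adjusted p = 0.51 with an estimated correlation), with Ier2 (-0.94 ± 0.22) the 1 member past the threshold over the list alone. Mesothelial genes, including Krt19, had a median of -0.73 (adjusted p = 0.0095), and the cadherin and catenin list, in which Cdh1 alone passed over the list, a median of -0.31 (adjusted p = 0.033). Both had adjusted p = 0.42 with an estimated correlation. With the Xist and Y covariate the cadherin and catenin median on the log2 CPM scale was 0.03 (camera adjusted p = 0.951) and the call ended. Acinar genes had a median of -5.33, or -3.92 with 4 members at their bound (adjusted p = 7.0e-06, and adjusted p = 0.50 with an estimated correlation), and 7 passed as lower over the list alone. This call ended without wild-type mouse 1, with the median on the log2 CPM scale between -3.57 and -1.11; the acinar sums were 410, 8.77 and 65.6 CPM in the wild-type and 26.3, 117 and 11.9 CPM in the labelled heterozygous tumours. Islet genes were higher (median 1.09, adjusted p = 0.0036, and adjusted p = 0.59 with an estimated correlation). Over all genes 1 passed, Trim12a (log2 5.67 ± 0.57, edgeR adjusted p = 0.017; 0.19 ± 0.31 with its copies summed). Smallest among those that did not pass were Trim30d (3.63 ± 0.61), H2-T23, Trem1 and the selectin ligand Selplg (1.89 ± 0.35). In the other direction were the histone demethylase Kdm2b (-1.28 ± 0.24), the transcription factor Zic2 (-8.44 ± 1.68), Paqr8 (-1.43 ± 0.29), Prag1 (-0.99 ± 0.21) and Mogat2 (-2.28 ± 0.49). An unadjusted p under 0.05 was reached by 1816 genes, against 1203 expected by chance, and DESeq2 called 237. With the Xist and Y covariate, which ran with genotype here, 479 genes reached it. With the acinar covariate 1961 did. The Trim12a call ended without any 1 of 5 of the 6 libraries, all except wild-type mouse 1, and with the replicate block, the acinar covariate or the Xist and Y covariate. The neutrophil and islet calls ended when any of 3 libraries was left out, among them wild-type mouse 3 and heterozygous mouse 2 for both. The cadherin call ended with any of 4 and the mesothelial and stress gene calls with 1. Of the 17 list calls 11 held with each library left out in turn, 14 with the acinar covariate and 6 with the Xist and Y covariate.

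**Figure D3:**
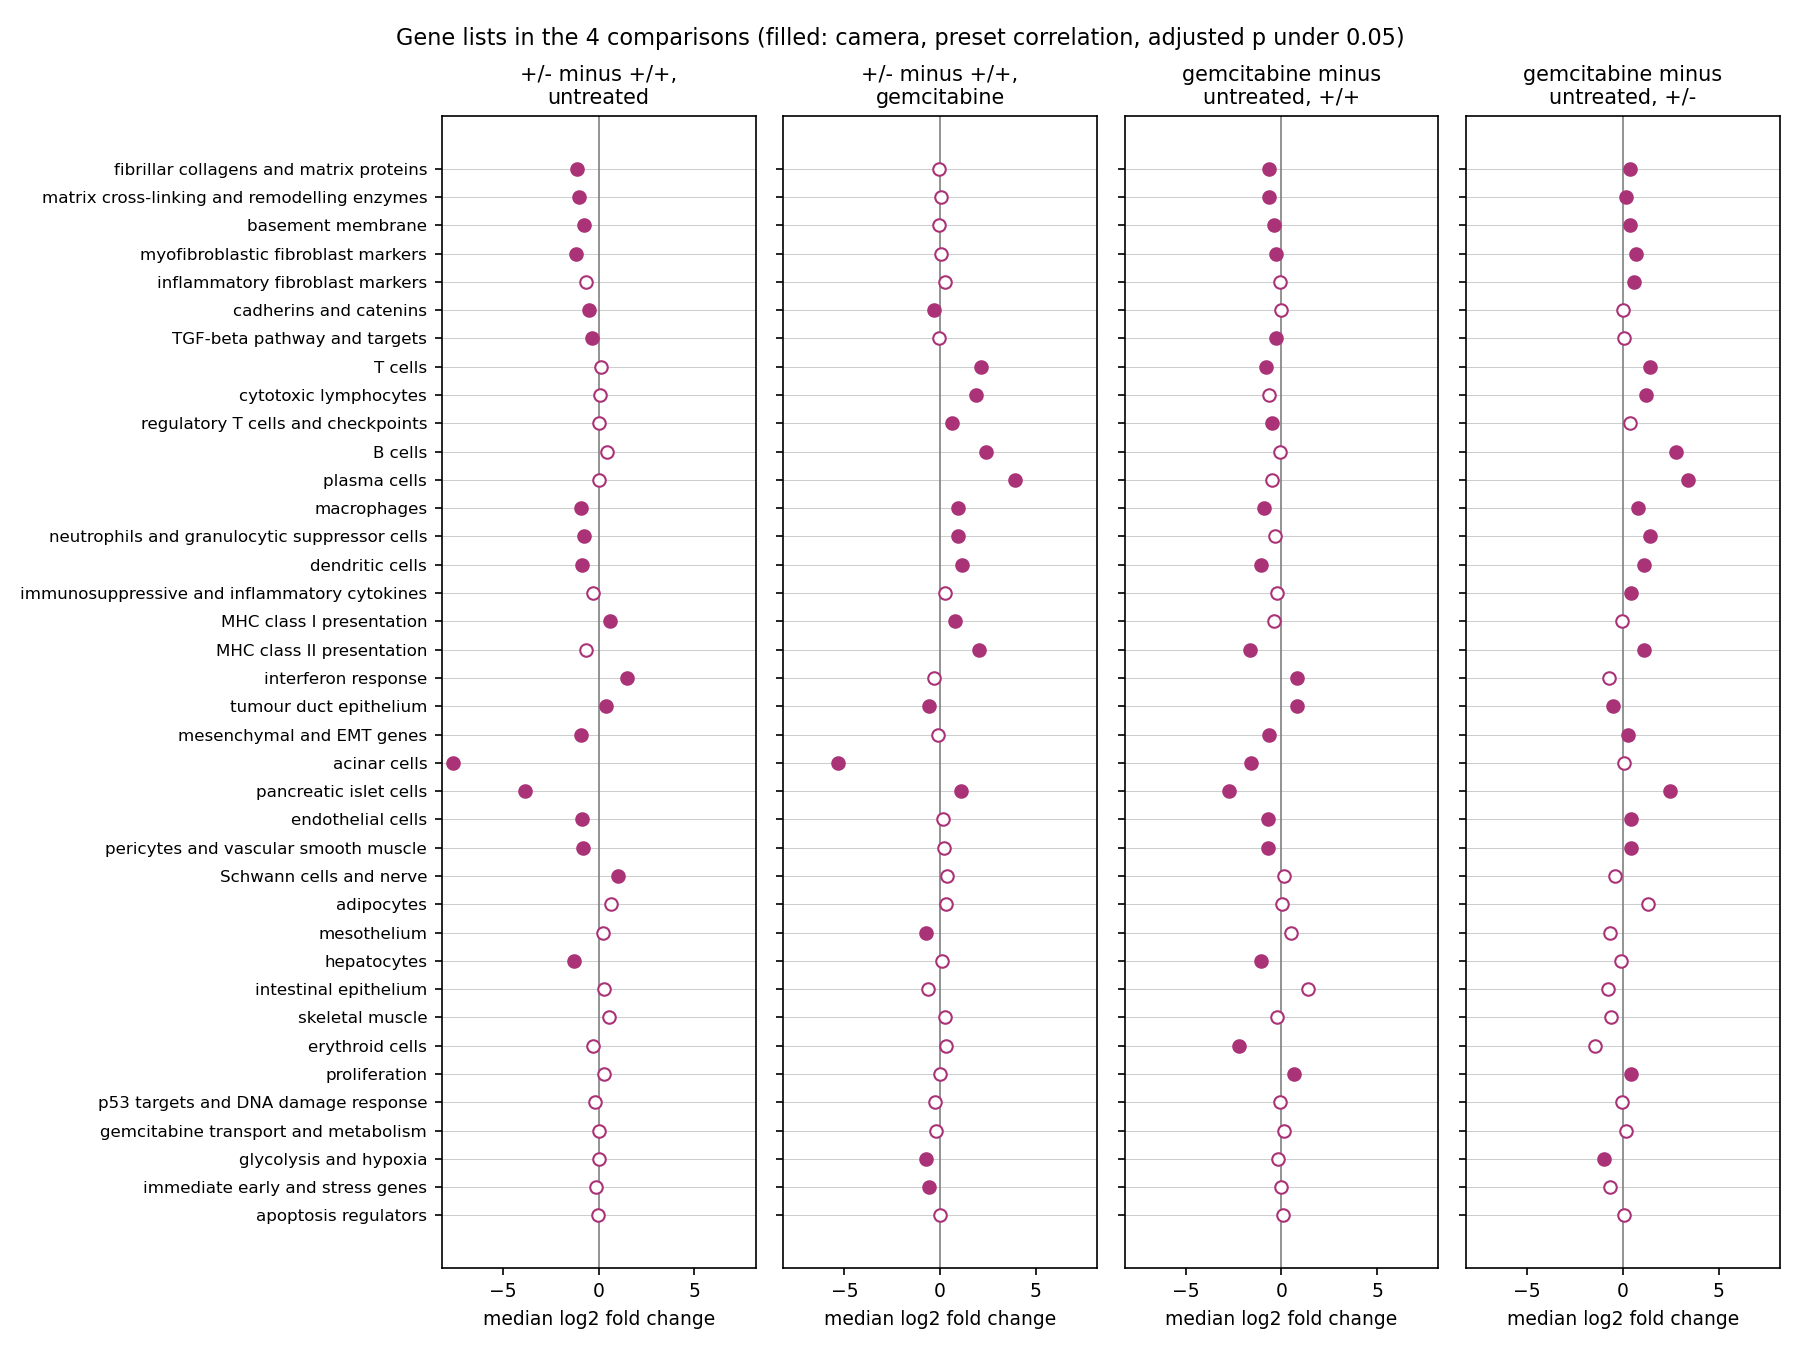
Median log2 fold change of the members of each of the 38 gene lists in the genotype comparisons and the gemcitabine comparisons; filled points were called by camera at its preset correlation and open points were not. Matrix lists lie below 0 in untreated heterozygous tumours and near 0 between treated groups, and the T cell, B cell and plasma cell medians lie at 2.16, 2.42 and 3.90 between treated groups; acinar medians include members with no count in a group.

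In wild-type mice, gemcitabine-treated tumours were compared with untreated tumours to ask what the drug does. Matrix and stromal genes were lower and duct epithelium genes higher in the treated tumours. Their RNA content differed too, with 7SL and 7SK RNA at 5.53% to 7.87% of the counts in untreated and 8.28% to 8.61% in treated tumours, and mitochondrial genes at 1.81 ± 0.469% and 2.62 ± 0.246%. Fibrillar collagens and matrix proteins were lower for 22 of 24 members (median -0.63, camera adjusted p = 1.1e-05, and adjusted p = 0.57 with an estimated correlation, as for the next 4 lists), and Lum passed over the list alone (-1.28 ± 0.32). Cross-linking and remodelling enzymes were lower for 22 of 24 members, median -0.67 (adjusted p = 1.3e-06), with Fap (-1.76 ± 0.42), Mmp11 (-1.28 ± 0.36) and Mmp13 (-4.33 ± 1.27) past the threshold over the list alone. Mesenchymal genes had a median of -0.66 (adjusted p = 0.0047), and Zeb2 (-1.01 ± 0.26), Tcf4 (-0.59 ± 0.17) and Prrx1 (-1.56 ± 0.45) passed over the list alone. Endothelial genes had a median of -0.68 (adjusted p = 1.4e-04), with Eng at -0.88 ± 0.25, and the TGF-beta list a median of -0.30 (adjusted p = 0.0085), with Tgfbi at -1.06 ± 0.38. Pericyte (-0.68), basement membrane (-0.40) and myofibroblast (-0.27) medians were called lower at adjusted p between 0.023 and 0.035, with adjusted p between 0.58 and 0.72 with an estimated correlation. These 3 calls ended with 2, 3 and 4 of the 6 libraries left out in turn, and the pericyte median on the log2 CPM scale ran from -0.85 to -0.20. Duct epithelium genes were higher for 17 of 22 members, median 0.79 (adjusted p = 2.8e-04, and adjusted p = 0.57 with an estimated correlation), with Krt7 at 1.20 ± 0.42 and the tight junction gene Ocln at 1.02 ± 0.33. Islet genes were lower (median -2.73, adjusted p = 2.3e-07, and adjusted p = 0.57 with an estimated correlation), as were acinar genes (median -1.60, adjusted p = 0.0046, and adjusted p = 0.73 with an estimated correlation). The acinar median on the log2 CPM scale went from -1.75 to -0.07 without treated mouse 2 and to -0.49 without untreated mouse 3, and the call ended with either left out.

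Macrophage genes were lower for 19 of 20 members in treated wild-type tumours, median -0.89 (adjusted p = 2.5e-04, and adjusted p = 0.58 with an estimated correlation), with Csf1r at -1.13 ± 0.45 and the complement gene C1qb at -1.07 ± 0.45. All 12 class II genes were lower, median -1.63 (adjusted p = 0.0047, and adjusted p = 0.70 with an estimated correlation). Dendritic cell genes had a median of -1.07 (adjusted p = 0.0036, and adjusted p = 0.64 with an estimated correlation), T cell genes -0.80 (adjusted p = 0.024, and adjusted p = 0.73 with an estimated correlation) and regulatory T cell and checkpoint genes -0.49 (adjusted p = 0.023, and adjusted p = 0.57 with an estimated correlation). Interferon response genes were higher for 21 of 27 members, median 0.82 (adjusted p = 0.0015, and adjusted p = 0.72 with an estimated correlation). The interferon regulator Irf7 was at 6.43, 10.3 and 68.9 CPM in the treated and 5.54, 5.30 and 2.33 CPM in the untreated tumours. Proliferation genes were higher for 23 of 24 members, median 0.68 (adjusted p = 0.023, and adjusted p = 0.82 with an estimated correlation), erythroid genes had a median of -2.20 (adjusted p = 0.0029) and hepatocyte genes -1.06 (adjusted p = 0.021). The last 2 had adjusted p = 0.57 with an estimated correlation. Genes of gemcitabine transport and metabolism were not called (median 0.15, adjusted p = 0.25). The nucleoside transporter Slc28a2 had 1.97 ± 0.66, and cytidine deaminase Cda, which inactivates gemcitabine, had -1.21 ± 0.51. The p53 target list had a median of -0.07 (adjusted p = 0.81); Trp53inp1 passed over the list alone (-0.91 ± 0.22). Over all genes, edgeR's quasi-likelihood test called 0 genes (smallest adjusted p = 0.56) and DESeq2 called 120. Another split of these libraries gave 189 by DESeq2. In all 2070 genes had an unadjusted p under 0.05, or 1343 with the acinar covariate and 1450 with the Xist and Y covariate. Smallest were Qtrt1 (1.36 ± 0.23), Snord22 (0.97 ± 0.18), the mitochondrial creatine kinase Ckmt1 (2.66 ± 0.50), Tmem266 (3.49 ± 0.67) and Dnajc22 (1.59 ± 0.33). Slitrk5 (-5.70 ± 0.87), Cyp7b1 (-2.36 ± 0.41), the haem-regulated repressor Bach1 (-0.87 ± 0.16) and Kank4 (-3.75 ± 0.71) lay in the other direction. The pseudogene Rpl7a-ps11, with no count in treated wild-type tumours, was at least 89.1-fold lower at 3 counts per library and did not pass. Without untreated wild-type mouse 2 the macrophage, dendritic, class II, T cell, regulatory T cell, basement membrane and pericyte calls ended and the class II median on the log2 CPM scale went from -0.93 to 0.06, and without treated wild-type mouse 2 the proliferation median went from 0.43 to -0.04. Untreated wild-type mouse 2 was the only Y-high library of these 6 (Y-linked genes 217 CPM, Xist 0.861 CPM). For the calls that ended without it, gemcitabine cannot be told apart from this mouse and its sex-chromosome genes. Of the 20 list calls 7 held with each of the 6 libraries left out in turn, and the interferon call ended without treated or untreated mouse 3. The acinar covariate left 13 of the 20 called, and the Xist and Y covariate 14.

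In heterozygous mice, tumours of gemcitabine-treated mice labelled heterozygous were compared with untreated heterozygous tumours. Most lists of immune cells were called higher in the treated tumours. Class I presentation (median -0.02) and regulatory T cell and checkpoint genes (0.39) were not called. Stromal lists were called higher too, though none of them with every library left out in turn. RNA content ran the other way from wild-type mice, with 7SL and 7SK RNA at 8.19% to 9.59% of the counts in untreated and 7.26% to 8.52% in treated tumours, and mitochondrial genes at 2.88 ± 0.876% and 2.29 ± 0.448%. Gm26917 lay at 1.25% to 2.37% in untreated and 0.320% to 0.729% in treated tumours. Macrophage genes were higher for all 20 members (median 0.79, camera adjusted p = 1.2e-05, and adjusted p = 0.54 with an estimated correlation, as for the next 6 lists), with Adgre1, the F4/80 antigen gene, at 1.43 ± 0.54 and Msr1 at 1.19 ± 0.40. Neutrophil genes were higher for 17 of 18 members, median 1.44 (adjusted p = 1.2e-05), and 6 passed when adjusted over the list alone, among them Trem1 (1.36 ± 0.33), S100a8 (1.67 ± 0.52), S100a9 (2.08 ± 0.67) and the chemokine Cxcl3 (4.33 ± 1.40). B cell genes had a median of 2.77 (adjusted p = 1.2e-05), T cell genes 1.43 (adjusted p = 7.5e-05), dendritic cell genes 1.08 (adjusted p = 3.8e-04) and class II genes 1.08 (adjusted p = 8.0e-04). Plasma cell genes had a median of 3.43 (adjusted p = 7.5e-05), with 4 past the threshold over the list alone, Ighg2c (6.94 ± 1.85), Igha (3.20 ± 0.94), Igkc (4.25 ± 1.32) and Jchain (3.71 ± 1.15). Treated mouse 1 lay within the untreated range of mean log2 CPM for B cells (-0.96, untreated -1.55 to 0.83), T cells (-0.38, untreated -0.88 to 1.17), plasma cells (2.09, untreated 1.25 to 3.58), class II genes (3.86, untreated 2.71 to 5.15), dendritic cells (1.12, untreated 0.50 to 1.81) and cytotoxic lymphocytes (-2.77, untreated -3.03 to -1.08), so that these 6 differences rest on mice 2 and 3. The class II call ended without untreated mouse 2. Cytotoxic lymphocyte genes had a median of 1.23 (adjusted p = 0.013, and adjusted p = 0.55 with an estimated correlation). The cytokine list had a median of 0.42 (adjusted p = 0.042, and adjusted p = 0.54 with an estimated correlation), with Csf2, encoding GM-CSF, at 2.12 ± 0.71 and Il1b at 1.78 ± 0.86; this call ended with any 1 of the 6 libraries left out (median on the log2 CPM scale 0.10 to 0.77). Fibrillar collagens and matrix proteins had a median of 0.37 (adjusted p = 0.0045, and adjusted p = 0.57 with an estimated correlation), with Lum at 0.78 ± 0.31, and the call ended without untreated mouse 3 or treated mouse 1 (median on the log2 CPM scale 0.13 to 0.60). Remodelling enzymes had 0.15 (adjusted p = 0.017, and adjusted p = 0.59 with an estimated correlation), with Timp1 at 0.83 ± 0.30; without untreated mouse 3 their median on the log2 CPM scale went from 0.29 to -0.08, and the call ended without untreated mouse 1, untreated mouse 3 or treated mouse 1.

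Myofibroblast markers were higher for 14 of 16 members, median 0.70 (adjusted p = 7.5e-05, and adjusted p = 0.54 with an estimated correlation, as for the next 5 lists), with Acta2 (1.26 ± 0.34) and Tagln (1.09 ± 0.31) past the threshold over the list alone. Inflammatory fibroblast (0.59), endothelial (0.45), pericyte (0.42), basement membrane (0.38) and mesenchymal (0.27) medians were called higher at adjusted p between 0.0016 and 0.023. The mesenchymal call ended without untreated mouse 1, untreated mouse 3 or treated mouse 1 (median on the log2 CPM scale 0.07 to 0.79). Islet genes were higher (median 2.46, adjusted p = 6.0e-04, and adjusted p = 0.54 with an estimated correlation), and acinar genes were not called (median 0.06, or 0.08 with 7 members at their bound, adjusted p = 0.86). Duct epithelium genes were lower for 19 of 22 members, median -0.49 (adjusted p = 0.0044, and adjusted p = 0.54 with an estimated correlation), with the trefoil factor Tff1 at -2.57 ± 0.86. Glycolysis and hypoxia genes were lower for 22 of 23 members, median -0.98 (adjusted p = 0.0016, and adjusted p = 0.59 with an estimated correlation), with Car9 at -1.34 ± 0.41. Untreated mouse 2 had a mean log2 CPM of 8.02 on this list against 6.23 and 6.21 in the other untreated mice; without it the median on the log2 CPM scale went from -0.67 to 0.03 and the call ended. Proliferation genes were higher for 22 of 24 members, median 0.41 (adjusted p = 0.0016, and adjusted p = 0.59 with an estimated correlation). This call ended without untreated mouse 1, untreated mouse 2 or treated mouse 2 (median on the log2 CPM scale 0.26 to 1.21). Interferon response genes had a median of -0.71 and were not called (adjusted p = 0.19), nor were p53 targets (-0.05, adjusted p = 0.77). Over all genes 2 passed, both higher. BC023719 was at 2.75 ± 0.10 CPM in treated tumours and at 0 in untreated, at least 43.4-fold higher at 3 counts per library (edgeR adjusted p = 8.6e-04, ended with voom and with only these 6 libraries in the model, at 0.191 and 0.201), and Gm10260, named as above, had a log2 fold change of 6.70 ± 0.44 (adjusted p = 2.0e-04). With copies summed these became 0.86 ± 0.37 and -0.39 ± 0.35. Lrat (4.84 ± 0.74, adjusted p = 0.25), Dach1 (1.92 ± 0.33), H2-Q1 (4.26 ± 0.74) and Rps18-ps3 (6.15 ± 1.11) came next and did not pass. Hectd2 (-1.36 ± 0.24), Prag1 (-1.09 ± 0.21), Gstp2 (-2.72 ± 0.61), the ER stress gene Herpud1 (-0.98 ± 0.22) and the acetyl-CoA synthetase Acss2 (-1.07 ± 0.25) were the smallest in the other direction. An unadjusted p under 0.05 was reached by 1901 genes, or 1019 with the Xist and Y covariate and 1843 with the acinar covariate. DESeq2 called 170 genes, and 394 in another split of these libraries. Of the 21 list calls 7 held with each of the 6 libraries left out in turn, those of macrophages, neutrophils, dendritic, T, B, plasma and islet cells, and without untreated mouse 1 or mouse 3 as many as 8 ended. Untreated mouse 1 was the only Xist-high library of these 6 (Xist 2000 CPM). The Xist and Y covariate left 15 of the 21 called, and the acinar covariate 21.

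The difference of the gemcitabine effects asks whether the drug acts otherwise in the 2 genotypes. Matrix, vascular, immune and islet genes had higher gemcitabine effects in heterozygous than in wild-type mice. RNA content moved with them, as 7SL and 7SK RNA went from 6.58% to 8.47% of the counts with gemcitabine in wild-type and from 8.74% to 7.78% in heterozygous mice, and mitochondrial genes from 1.81% to 2.62% and from 2.88% to 2.29%. For all 24 fibrillar collagens and matrix proteins the difference was above 0, with a median of 0.89 (camera adjusted p = 3.8e-06, and adjusted p = 0.36 with an estimated correlation). Lum passed over the list alone (2.06 ± 0.44). The mean log2 CPM of this list was 9.26 in untreated wild-type and 8.16 in untreated heterozygous tumours. In treated tumours it was 8.595 in the wild-type and 8.594 in the labelled heterozygous group, so the difference lies between the untreated groups. For all 20 macrophage genes it was above 0, median 1.68 (adjusted p = 2.6e-07, and adjusted p = 0.36 with an estimated correlation), and 5 passed over the list alone, including Mrc1 (2.31 ± 0.68) and Chil3 (4.60 ± 1.41). All 16 endothelial genes (median 1.08), all 14 dendritic cell genes (2.23), all 19 T cell genes (1.89) and all 12 class II genes (2.80) also lay above 0, with adjusted p between 1.1e-05 and 6.0e-05, and with adjusted p = 0.36 with an estimated correlation. Among them 4 endothelial genes passed over the list alone, Eng (1.66 ± 0.35), Cdh5 (1.16 ± 0.28), Erg (1.62 ± 0.43) and Pecam1 (1.12 ± 0.36). Trem1 (2.76 ± 0.47) and S100a8 (2.65 ± 0.73) were among 4 neutrophil genes past the threshold over the list alone. Zeb2 (1.89 ± 0.37) was the 1 mesenchymal gene past it, and Vsir (1.89 ± 0.47), an inhibitory receptor, and Entpd1 (1.29 ± 0.37) were the 2 checkpoint genes. Of 19 islet genes 12 passed as higher and 1 as lower over the list alone, with a median of 5.17 (adjusted p = 1.6e-07, and adjusted p = 0.36 with an estimated correlation). Duct epithelium (median -1.13, adjusted p = 3.0e-05) and interferon response genes (-1.76, adjusted p = 0.0028) differed the other way, with adjusted p = 0.36 and adjusted p = 0.62 with an estimated correlation. Glycolysis and hypoxia genes did too (-0.72, adjusted p = 0.0091, and adjusted p = 0.67 with an estimated correlation), and Car9 was the 1 member past the threshold over the list alone (-3.03 ± 0.59). The glycolysis call ended with any of 3 libraries left out (median on the log2 CPM scale -1.09 to -0.13), and the interferon call without untreated heterozygous mouse 3 (-1.99 to -0.66). Over all genes 2 passed, BC023719 (9.65 ± 0.77, a fitted value that rests on a group at 0) and Gm10260 (5.82 ± 0.52), both with edgeR adjusted p = 0.0048; the BC023719 call ended with voom (0.164). Their sums with copies differed by 0.58 ± 0.51 and -0.87 ± 0.49. Lrat (7.01 ± 0.97), Cyp7b1 (3.89 ± 0.57), Naalad2 (2.21 ± 0.34) and Trem1, and in the other direction Qtrt1 (-2.30 ± 0.32), Snord22 (-1.67 ± 0.25), Ckmt1 (-3.87 ± 0.68), Eif3g (-1.37 ± 0.25) and Dnajc22 (-2.40 ± 0.46), did not pass. An unadjusted p under 0.05 was reached by 3046 genes, or 1455 with the Xist and Y covariate and 2433 with the acinar covariate. DESeq2 called 652. Of the 23 list calls 15 held with each of the 12 libraries left out in turn, and 6 ended without untreated wild-type mouse 2. Besides glycolysis and interferon the cytotoxic lymphocyte, inflammatory fibroblast, B cell, regulatory T cell, TGF-beta and acinar calls ended at least once. The Xist and Y covariate left 17 of the 23 called, and the acinar covariate 22. For T, B and plasma cells the rise in heterozygous mice rests on treated mice 2 and 3, as given above.

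**Figure D4:**
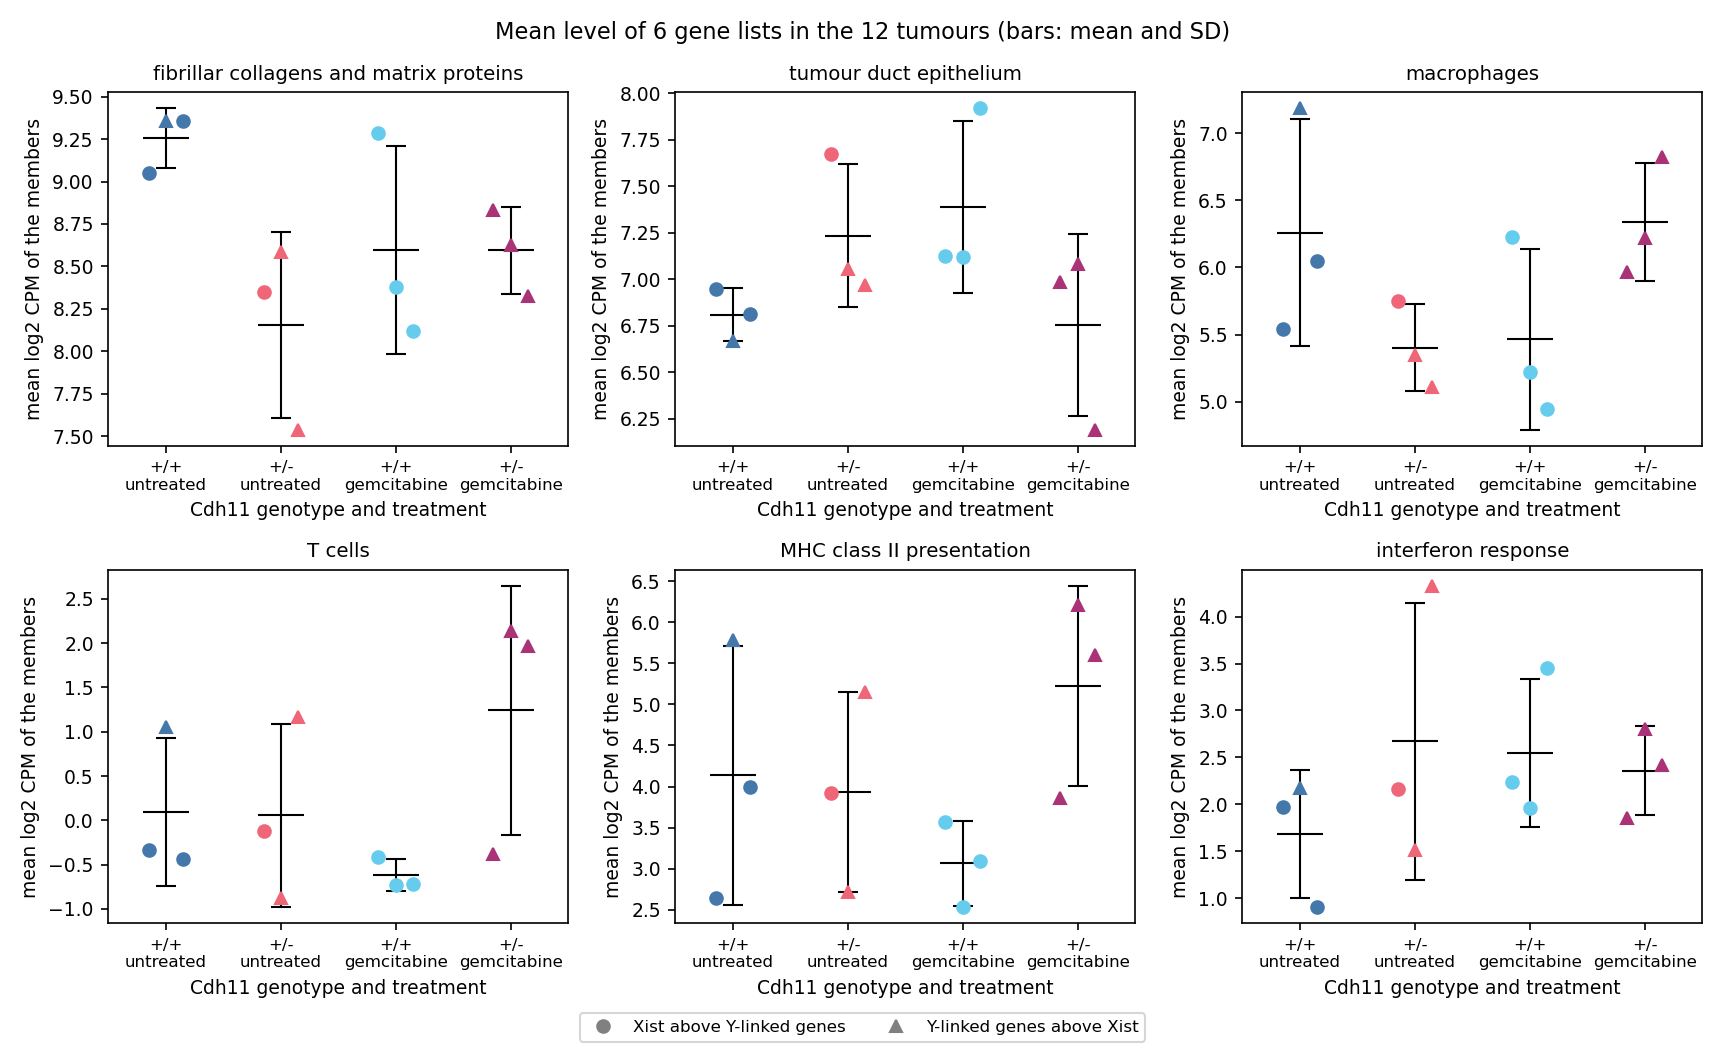
Mean log2 CPM of the members of 6 gene lists in each of the 12 tumours; horizontal bars are group means with SD (n = 3), and marker shape shows whether Xist or the Y-linked genes were higher. The fibrillar collagen list lies at 9.26 ± 0.18 in untreated wild-type and 8.16 ± 0.55 in untreated heterozygous tumours, and the T cell list at 1.24 ± 1.41 in treated tumours labelled heterozygous and -0.62 ± 0.18 in treated wild-type tumours, with treated heterozygous mouse 1 at -0.38; 1 untreated heterozygous tumour lies at 4.33 on the interferon panel.

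Averaged over both treatments, the genotypes were compared in all 12 libraries. H2-T23 on chromosome 17 and 3 TRIM genes on chromosome 7 were higher, and the matrix list lower, in heterozygous mice. H2-T23, a non-classical class I gene (chromosome 17, 36029773 to 36032855), had a log2 fold change of 2.25 ± 0.28 (edgeR adjusted p = 0.031), and 1.67 ± 0.23 (adjusted p = 0.048) with its near-identical copies summed. The H2-T23, Trim5, Trim30d, Rps13 and Gm11361 calls each ended with the acinar covariate and with the Xist and Y covariate (0.170 and 0.754 for H2-T23). Trim12a (5.91 ± 0.41, adjusted p = 1.5e-04), Trim5 (3.66 ± 0.51) and Trim30d (3.00 ± 0.42) lie together on chromosome 7 between 104263386 and 104507849, and Rps13 (1.57 ± 0.20) lies at 116331505 on the same chromosome. With copies summed these 4 differed by 0.25 ± 0.22, 0.25 ± 0.22, 0.74 ± 0.32 and 0.10 ± 0.18, and none passed. BC023719, with no count in untreated heterozygous tumours (adjusted p = 4.0e-04), Gm10260 (-4.23 ± 0.28, adjusted p = 1.5e-04) and Gm11361 (-7.32 ± 0.94, adjusted p = 0.032) were lower; with copies summed they differed by -1.36 ± 0.26, 0.18 ± 0.25 and 0.18 ± 0.25 and did not pass. Gm11361, like Gm10260, is a copy of Rps18 named after its values were seen. H2-Q1 (-3.30 ± 0.47, adjusted p = 0.053), Lrat (-2.92 ± 0.48) and the cornified envelope gene Ivl (-1.61 ± 0.27) did not pass. An unadjusted p under 0.05 was reached by 1845 genes, or 1053 with the Xist and Y covariate and 1199 with the acinar covariate. DESeq2 called 304. With each of the 12 libraries left out in turn the Trim12a, BC023719 and Gm10260 calls held throughout, and those of H2-T23, Rps13, Trim5, Gm11361 and Trim30d in 6, 5, 2, 1 and 0 of the 12.

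The genotype average called 9 lists higher and 15 lower, and 1 higher and 10 lower with the Xist and Y covariate, with which none of the 9 stayed called (T cells 0.46 on the log2 CPM scale, adjusted p = 0.0745). Fibrillar collagens and matrix proteins had a median of -0.62 (camera adjusted p = 6.1e-08, and adjusted p = 0.41 with an estimated correlation), and 6 passed over the list alone, including Lum (-0.85 ± 0.22), Col3a1 (-0.81 ± 0.25), Col6a3 (-1.21 ± 0.38) and Col1a1 (-1.20 ± 0.38). Acinar genes had a median of -6.90, or -5.15 with 7 members at their bound (adjusted p = 1.3e-14, and adjusted p = 0.35 with an estimated correlation), and 19 passed as lower over the list alone. T cell genes had a median of 1.05 (adjusted p = 1.5e-04, and adjusted p = 0.41 with an estimated correlation), with Cd5 (2.06 ± 0.42), Cd28 (2.04 ± 0.48) and Cd3e (3.36 ± 0.84) higher over the list alone and Thy1 (-0.89 ± 0.28), which fibroblasts also express, lower. Summed T cell genes did not follow this median. They lay at 83.6 to 108 CPM in untreated heterozygous and 163 to 233 CPM in untreated wild-type tumours, and overlapped in treated mice. H2-Eb1 was the 1 class II gene past the threshold over the list alone (4.95 ± 0.91), and Cdh6 (-1.34 ± 0.37) and Cdh5 (-0.48 ± 0.14) the 2 cadherin genes. Across the comparisons, 0 of the list calls held with an estimated correlation and 0 by fry. Of the 24 calls 14 held with each library left out in turn, 13 with the acinar level in the model and 9 with Xist and Y-linked genes. Lists not called in any comparison were adipocytes (median 0.46 in the genotype average), skeletal muscle (0.46), intestinal epithelium (-0.56), apoptosis regulators (-0.12), p53 targets (-0.17) and gemcitabine transport and metabolism (-0.04).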

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

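The tests of summed H2-T23 copies, of gene positions and chromosome 8, of Xist and Y-linked genes in the gene lists and of the share of epithelium were chosen only after the result was seen. The acinar level and single libraries left out were planned as alternatives. Their use as explanations of the third pattern was also chosen after the result was seen.

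The gemcitabine effects differed between the genotypes, by the test of the difference itself, for 2 genes and 23 gene lists. BC023719 differed by 9.65, a fitted value against a group at 0, and Gm10260 by 5.82 on the log2 scale, heterozygous minus wild-type. Among matrix and stromal lists the median differences were 0.89 for fibrillar collagens and matrix proteins (-0.63 in wild-type and 0.37 in heterozygous mice), 0.86 for remodelling enzymes, 0.76 for basement membrane, 1.14 for myofibroblast markers, 0.60 for inflammatory fibroblast markers, 0.27 for the TGF-beta list and 0.76 for mesenchymal genes. For vessels they were 1.08 for endothelial cells and 0.95 for pericytes. Among immune lists they were 1.68 for macrophages (-0.89 in wild-type and 0.79 in heterozygous mice), 2.06 for neutrophils, 2.23 for dendritic cells, 2.80 for class II presentation, 1.89 for T cells, 1.71 for cytotoxic lymphocytes, 0.62 for regulatory T cells and checkpoints, 2.62 for B cells and 3.96 for plasma cells. The difference was -1.76 for interferon response, -1.13 for duct epithelium and -0.72 for glycolysis and hypoxia. For tissue admixture it was 5.17 for islet cells and 1.90 for acinar cells, or 1.80 with 7 members at their bound; the acinar call ended with 8 of the 12 libraries left out (median on the log2 CPM scale 0.57 to 3.81) and the islet call with 0. The cytotoxic call ended with 5 (0.65 to 2.13), the inflammatory fibroblast call with 4, the B cell call with 3 (1.28 to 3.55), the glycolysis call with 3, the regulatory T cell call with 2 and the interferon and TGF-beta calls with 1. Camera adjusted p lay between 1.6e-07 and 0.040, and between 0.356 and 0.717 with an estimated correlation. Of 80 splits of the libraries, 9 gave at least 2 genes, the highest 8, and 4 gave at least 23 lists, the highest 24, so chance is not excluded for either count.

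The first pattern is the 9 genes called between genotypes. Summed counts argue against reads shared between near-identical copies as the whole source for H2-T23, which stayed past the threshold (log2 1.67, SE 0.232, edgeR adjusted p = 0.048, against 2.25 before). H2-T23 held 87.88% of the summed counts, and relatives under 95% identity were not summed. Before summing, its call held in 6 of 12 fits with 1 library left out and ended with the acinar and the Xist and Y covariates. Lrat, the 1 called gene without a near-identical copy, has none to share reads with. Of the 8 with a copy only 1 was called after summing; Trim12a went from 6.15 to 0.31 (SE 0.306) and Gm10260 from -7.14 to 0.61 (SE 0.347), so the calls ended because the folds shrank, and for these genes shared reads cannot be told apart from real differences between copies. The mice have a mixed C57BL/6 and 129 background, and strain haplotypes at a few loci are a candidate explanation. Among the 100 genes of smallest p for the genotype average, 67 pairs lay within 5 Mb. In 10000 random draws the 95th percentile was 36 and the highest value 71. There were 57 and 91 pairs for genotype in untreated and treated mice, and 41 and 56 for gemcitabine in wild-type and heterozygous mice. Both gemcitabine comparisons also exceeded that percentile, so the pairs cannot single out haplotypes. Changes in genes beside the Cdh11 allele, from sequence of the 129 strain, do not account for the calls, since 0 of the called genes lie on chromosome 8. Effects of that sequence on genes of other chromosomes were not tested. Of the 100 genes 15 lie on chromosome 7, against 7.81 expected.

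The second pattern is the higher level of 10 lists of immune cells and antigen presentation in treated mice labelled heterozygous; the interferon response (median -0.32, adjusted p = 0.50) and cytokine lists (0.28, adjusted p = 0.92) were not called. No list of this comparison was called with an estimated correlation (lowest adjusted p = 0.424) or by fry. A lower share of tumour epithelium, if it raised stromal and immune lists alike, is argued against. The median of the stromal list medians was 0.16 (from -0.07 to 0.34) against 0.61 to 3.90 for the immune lists. Stroma need not rise with immune cells, however, and the duct epithelium list was lower (median -0.58). Immune cells in place of epithelium therefore cannot be excluded by these medians. With Xist and Y-linked genes in the model 4 of the 10 lists stayed called, but all treated wild-type mice were Xist-high and all those labelled heterozygous Y-high, so sex and genotype cannot be told apart there. The genotype, the litter and the place of sampling in the tumour remain open and untested. The 10 splits of 6 libraries are too few for a share under 0.05, with 17 lists called in the real split and 16 in the highest other.

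The third pattern is the lower matrix lists in untreated heterozygous mice. With the acinar level in the model the fibrillar collagen median on the log2 CPM scale moved from -1.24 to -0.60. The list stayed called at the preset correlation (camera adjusted p = 2.7e-04), and no list is called with an estimated one. Acinar tissue in wild-type samples may therefore account for part of the difference. Whether it accounts for the whole cannot be told, since 6 of the 24 acinar genes behind the level had no count in a group. With each heterozygous library left out the median nearest 0 was -0.84, which argues against 1 library as the source. A higher share of tumour epithelium would lower every other cell type, while the Schwann cell list was called higher, at 0.99, with adjusted p = 0.279 with an estimated correlation. Its median on the log2 CPM scale stayed between 0.60 and 0.77 with 1 library left out, and the call ended without heterozygous mouse 3 (0.65, adjusted p = 0.076). The duct epithelium list was itself higher (median 0.36), so this 1 list does not exclude a higher share of epithelium. The genotype remains open, and the 10 splits are too few for a share under 0.05, with 19 lists in the real split and 20 in the highest other.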

How the results depend on the processing

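The Xist and Y-linked covariate in the gene list tests was chosen only after the result was seen, unlike the other tests here. Counts of genes moved most with the test: DESeq2 called 703 genes for genotype in untreated mice, 120 and 170 for gemcitabine in wild-type and heterozygous mice, 237 for genotype in treated mice, 652 for the difference of effects and 304 for the genotype average, against 4, 0, 2, 1, 2 and 8 with edgeR. Other splits of the same libraries gave DESeq2 counts as high as 474, 189, 394 and 162 for the first 4 of these comparisons. With voom and quality weights the counts were 2 for genotype in untreated mice, 1 for gemcitabine in heterozygous mice and 1 for the difference. Without a low-count filter 10 genes passed for genotype in untreated mice. With only the 2 groups compared, 2 passed for genotype in untreated and 12 in treated mice. With the acinar covariate 0 passed for genotype in treated mice and 3 for the genotype average, and with the Xist and Y covariate 0 and 3. Gene lists called with the Xist and Y covariate were 9 for genotype in treated mice and 11 for the genotype average. With an estimated correlation between genes 0 lists were called in all 6 comparisons, and by fry 0. Except where the construction shows it, as with fewer libraries, the cause was not tested.

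With the replicate block 0 genes passed for genotype in treated mice and 4 for the genotype average, and the list counts of the 6 comparisons were 20, 20, 21, 17, 22 and 23. The numbers do not pair the samples: 4 of 18 same-numbered pairs correlated over 0.1, from -0.247 to 0.173, and the same number was the best match in 6 of 18. With each library left out in turn, genes ranged from 2 (without untreated wild-type mouse 1) to 12 (without untreated heterozygous mouse 1) for genotype in untreated mice, 0 to 0 and 2 to 9 for gemcitabine in wild-type and heterozygous mice, 0 to 3 for genotype in treated mice, 2 to 7 for the difference and 3 to 13 for the average. Lists ranged from 15 to 20, 14 to 21, 15 to 19, 13 to 20, 18 to 24 and 16 to 24 in the same order.

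Some directions reversed, and the cause was not tested. The Cdh11 difference between treated groups was 0.00085 with upper quartile normalization, 0.29 with the acinar covariate and 0.017 with the Xist and Y covariate, and ranged from -0.30 to 0.22 with 1 library left out; for gemcitabine in heterozygous mice it ranged from -0.31 to 0.19. With the Xist and Y covariate, medians on the log2 CPM scale became 0.027 for cadherins and catenins and 0.023 for class I presentation between treated groups, and -0.18 for cytotoxic lymphocytes and -0.016 for regulatory T cells in the genotype average. The islet median of that average became 0.67 with the acinar covariate. With 1 library left out the class I median in untreated mice ranged from -0.28 to 0.73, the interferon median from 0.11 to 1.33 there and from -0.023 to 0.62 in the genotype average, and the proliferation median for gemcitabine in wild-type mice from -0.043 to 0.99. Medians also changed sign for dendritic cells in untreated mice (-1.01 to 0.19), class II presentation with gemcitabine in wild-type mice (-1.77 to 0.055), and remodelling enzymes (-0.084 to 0.80) and glycolysis (-0.99 to 0.033) with gemcitabine in heterozygous mice. Among single lists, by the direction given by camera, which need not be the sign of the median, 855 values kept direction and call and 167 kept direction alone with 1 library left out, and 296 and 319 under the other alternatives. Among single genes these were 149 and 56, and 161 and 31. The single genes include Cdh11, which was not called in any comparison and counts as kept where it stayed uncalled. The 149 and 161 therefore do not count kept calls alone. The alternative with expected counts left unrounded could not be run, since the deposited values were already whole. Of simulated 2-fold changes the test recovered at most 34%, so changes of that size can be missed at this spread between mice.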

Other observations

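No test in this part was chosen only after the result was seen, and the gene values below come from the fixed lists.

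Single members of other lists passed over their list alone for the difference of the gemcitabine effects, heterozygous minus wild-type. The carbonic anhydrase Car9, a hypoxia target, was at 14.0 ± 7.07 CPM (SD, n = 3) in untreated wild-type, 34.8 ± 13.4 in untreated heterozygous, 45.2 ± 6.21 in treated wild-type and 13.8 ± 5.32 in treated tumours labelled heterozygous. In wild-type mice alone Car9 passed over the glycolysis list (1.70 ± 0.42, SE). Trp53inp1, a p53 target, differed by 1.31 ± 0.32 and was the 1 member past the threshold over its list alone. The adipocyte regulator Pparg differed by -1.99 ± 0.54 and was also the 1 member past it. The plasma protein genes Trf, for transferrin, and Hp, for haptoglobin, differed by 2.53 ± 0.62 and 3.28 ± 0.95, the 2 hepatocyte list members past it, while the list itself was not called (camera adjusted p = 0.066). Vil1, the villin gene of brush borders, was the 1 intestinal gene past the threshold over the list alone with gemcitabine in wild-type mice (1.39 ± 0.33). None of these genes passed over all genes. Passing over a list alone was not corrected for the number of lists and comparisons, so chance is not excluded for these single members.

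Cdh11 was compared with the matrix genes of the same libraries, to ask whether less matrix-producing stroma could account for its lower level in untreated heterozygous mice. Cdh11 minus the mean of the fibrillar collagen list was -1.48 ± 0.442 (SD, n = 3) in wild-type and -1.40 ± 0.307 in heterozygous tumours, a difference of 0.078 log2 units (two-sided exact permutation p = 0.8, where 0.1 is the smallest this design can give). In treated mice the difference was 0.01 (exact permutation p = 1). The value is consistent with Cdh11 and matrix genes being lower together, and it does not say which of them comes first.

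Sequence of the 129 strain carried along with the Cdh11 allele might change genes near it. Of 256 tested genes within 10 Mb of Cdh11, 19 (7.42%) had an unadjusted p under 0.05 for the genotype average, against 7.66% of the other genes (one-sided Fisher's exact p = 0.591), which argues against a wide change around the allele in that average. The average includes the treated mice, in which Cdh11 did not separate the labelled genotypes.

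Other splits of the libraries were compared with the real ones. For genotype in untreated mice 4 genes passed in the real split and 7 in the highest other, which parted Xist-high from Y-high libraries (5 genes passed in the real split with the Xist and Y covariate); 2 of 10 splits gave as many genes and 2 as many lists. For gemcitabine in wild-type mice edgeR gave 0 genes in all 10 splits, with 2070 genes at an unadjusted p under 0.05 and 120 called by DESeq2 in the real split, and 20 lists against 16, reached by 1 split, the real one. For gemcitabine in heterozygous mice there were 2 genes against 1, and 21 lists against 21. For genotype in treated mice there was 1 gene against 1, in 2 of 10 splits. In these 4 comparisons 10 splits are too few for a share under 0.05. Among the other splits DESeq2 called as many as 474, 189, 394 and 162 genes, in the order above. In the real splits it called 703, 120, 170 and 237. For the genotype average 8 genes were reached by 1 of 80 splits, the real one, with 4 in the highest other. As many as 24 lists were reached by 2 of 80, with 24 in the highest other. Both shares lay under 0.05, but they were not corrected for the 6 comparisons, so chance is not excluded. The median of the other splits was between 10 and 15 lists. In the real splits 0 lists were called with an estimated correlation between genes. That correlation was not estimated in the other splits, and a structure of the samples beside the groups was not tested as the source of these counts.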
